A study of Rattus norvegicus with 10 samples.

How the data were processed

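Tissue RNA from the AAR was sequenced as stranded, polyA-selected libraries at 4 h and 24 h, 2 per group, and nuclei from the AAR as 1 library per group at 24 h. According to the submitters' processing notes, reads were trimmed with Trim Galore, aligned to the rat build Rnor_6.0 with STAR and counted with featureCounts, and nuclear reads were processed with Cell Ranger, version 8.0.1 per the file headers. The versions of the other tools, the strand setting of the counting, the annotation release and whether intronic reads were counted are not given in the sources used here. Values of genes that overlap on opposite strands or have near-identical copies (Hspa1a, Ifit1bl, Ces1d) are therefore uncertain. The authors deposited raw counts per gene and tissue library for 31580 genes, and UMI counts per gene and barcode for 39537 nuclear features. The deposited barcodes were a called set, with a lowest depth of 500 UMIs. Each column was assigned to its library through the column name given in the sample descriptions, and 0 columns stayed unassigned.

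Tissue counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (15216 genes), libraries were scaled by TMM factors, and a quasi-likelihood model with 1 mean per group was fitted to all 8 libraries with robust dispersion, which left 4 residual degrees of freedom. The biological coefficient of variation was 14.3%. The contrasts were BT2 against vehicle at 4 h and at 24 h, the difference between these effects, and 24 h against 4 h in vehicle and in BT2. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was called. The sample numbers were not treated as pairs, since nothing states a pairing. Deviations of equal-numbered libraries from their group means correlated across genes at values from -0.046 to 0.097.

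Before the data were examined, 35 gene lists and the cell type markers were fixed, with 737 entries, of which 702 matched by symbol, 3 by an older or newer symbol and 32 did not match. A reference table of gene names on a later assembly (GRCr8) was used for names alone. Lists with at least 4 tested members (34 lists) were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry. Member counts are given over all genes tested and adjusted over the list alone. The rule for named genes was also fixed before. It took genes with a proper symbol, a mean of at least 5 CPM, an adjusted p under 0.05 and both libraries of one group above both of the other, and kept the 8 largest and 8 smallest log2 fold changes (6 and 6 for the contrasts of time). It added up to 2 called members of each list with the smallest p, and for the difference between the effects it took the 5 smallest p in each direction. Fosb, Fos, Egr1, Vcam1, Il6, Ccl2, Nppa and Nppb were reported in any case. Further list members (C1qa) were named after their values were seen.

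Nuclei with at least 500 UMIs, 200 genes and at most 5% mitochondrially encoded UMIs were kept, 11371 in vehicle and 10324 with BT2. Scrublet (expected rate 0.08) marked 1 and 0 nuclei as doublets, so its automatic threshold removed almost none and doublets are not excluded. Counts were scaled to 10000, log-transformed and reduced to 2000 variable genes and 30 principal components, without integration of the libraries, with scanpy 1.11.5 in Python 3.11.15. Leiden clustering (15 neighbours, resolution 0.5) gave 21 clusters. A cluster was named after the cell type with the highest marker score where the score was at least 0.9, led the next unrelated type by 0.5, rested on at least 3 detected markers and the median doublet score was at most 0.1. These limits were set after the clusters were seen, and 5 clusters stayed unnamed, 4 of them for a high doublet score. Shares of nuclei carry exact (Clopper-Pearson) 95% intervals. Within the 9 classes with at least 100 nuclei in each library, UMIs were summed and CPM ratios of BT2 over vehicle given with exact intervals from the Poisson model. Named nuclear genes had at least 50 UMIs in the higher library and the 6 largest or 6 smallest ratios of their class. The 8 genes above were reported from 10 UMIs in both libraries together. The median of a list was placed among 10000 random lists of the same size matched on expression. These intervals and percentiles cover counting error or gene choice, not differences between animals, and no p-value was computed for nuclei. Classes that joined several clusters were also compared cluster by cluster, which was chosen after the class values were seen.

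Tissue counts were simulated from a negative binomial model, with the mean CPM of each gene over all libraries and the fitted dispersions. There edgeR recovered 65.2% of planted 2-fold changes at 4 h and 65.7% at 24 h, and 92.5% and 98.6% of 4-fold changes. At 4 h 15 of 129 calls were false and at 24 h 17 of 145. The planted list was called and 0 of 40 random lists were. Genes were drawn independently, so this says nothing on list calls under correlation between genes. In the data those calls depended on it, with 0 lists called by camera under an estimated correlation. Nuclear counts were drawn from the Poisson model that the intervals assume, so a coverage near 95% was fixed in advance. Between 95.5% and 96.1% of the intervals over all simulated genes held the true ratio. For genes with a planted change it was between 95% and 97.5%. Spread between nuclei or animals was not simulated.

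The alternatives were RLE and upper quartile factors, no filter, a filter of 50 counts in 2 libraries, DESeq2 1.42.0, a minimum of 2-fold, the replicate number as a block, fits of 1 time alone and each library left out in turn, where a group left with 1 library is assumed to vary like the others. For nuclei they were Leiden resolutions of 0.3 and 1, stricter limits (1000 UMIs and 1% mitochondrial UMIs), doublets kept, thinning to 1000 UMIs and, chosen after the data were seen, removal of the nuclei with the highest 8% of Scrublet scores (1880 nuclei). Log2 ratios centred on the median gene and shares without cardiomyocyte-like nuclei were also among them. The mitochondrially encoded genes had 0 tested members in tissue and were left out there.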

Results

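RNA was measured in the area at risk (AAR) of rat hearts, the myocardium that loses its blood supply when the left coronary artery is tied and regains it at reperfusion. The animals received vehicle or BT2, a small molecule known here by its code name only. Polyadenylated tissue RNA was sequenced as 8 libraries, with 2 libraries for each of vehicle and BT2 at 4 h and at 24 h. Single nuclei were profiled at 24 h, with 1 library from vehicle and 1 from BT2 (100 mg/kg). The dose of the tissue samples is not given in the sources used here. The sample titles count the hours from ligation and the series text counts them from the ischaemia and reperfusion injury, so the zero point of the 4 h and 24 h times stays open. Total counts were 10397310 and 17696344 in the vehicle libraries at 4 h and 13735630 and 19171154 with BT2. At 24 h they were 24480984 and 20813410 in vehicle and 20767609 and 21648965 with BT2. Across genes, the replicate libraries of a group correlated at r = 0.987 (vehicle) and 0.990 (BT2) at 4 h and at 0.994 and 0.991 at 24 h. The nuclear libraries held 11540 (vehicle) and 10497 (BT2) barcodes with 45471510 and 32624251 UMIs. The sources used here do not say whether the libraries of a group came from separate animals, so a p-value measures the spread between these samples. Gene p-values are from edgeR and list p-values from limma's camera, each adjusted by the Benjamini-Hochberg method, and n = 2 libraries per tissue group throughout.

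The comparison at 4 h asked which AAR transcripts differed between BT2 and vehicle at the earlier time. Cytokine, chemokine, immediate early, cardiac stress and matrix protease transcripts were among those lower with BT2, and Cpt1a was among a smaller set that was higher. Csf2, which encodes the myeloid growth factor GM-CSF, fell by 3.37 ± 0.38 on the log2 scale (SE; edgeR adjusted p = 0.00919), from 10.2 ± 0.385 to 1.01 ± 0.474 CPM (counts scaled to the library size with TMM factors, mean ± SD). Osm, which encodes the cytokine oncostatin M, fell by 2.41 ± 0.18 (edgeR adjusted p = 0.00552), from 29.7 ± 1.02 to 5.56 ± 0.682 CPM. Cpt1a, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, rose by 1.32 ± 0.17 (edgeR adjusted p = 0.00954), from 41.1 ± 6.97 to 102.5 ± 13.2 CPM. In all, edgeR called 2495 of 15216 tested genes, 1015 higher and 1480 lower with BT2.

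Among genes of inflammation, Il1b (interleukin-1 beta) fell by 2.92 ± 0.63 at 4 h (edgeR adjusted p = 0.0281). Trem1, a receptor that amplifies neutrophil and monocyte responses, fell by 3.11 ± 0.56 (edgeR adjusted p = 0.0177). Fcar, the myeloid receptor for immunoglobulin A, had a log2 fold change of -3.36, Tarm1 of -2.82 and Tnfsf18, a ligand of the tumour necrosis factor family, of -3.06. The log2 fold change of Nlrp3, the inflammasome sensor, was -2.18 (edgeR adjusted p = 0.0179). Of 15 inflammatory cytokines 0 rose, 6 fell (8 when adjusted over the list alone) and 9 did not pass, with a median of -1.44 (camera adjusted p = 2.69e-05; adjusted p = 0.311 with an estimated correlation). Of 26 chemokines 0 rose, 8 fell (12 adjusted over the list alone), among them Ccl6 at -2.36 and Cxcl16 at -0.79, and 18 did not pass (camera adjusted p = 2.69e-05; adjusted p = 0.284 with an estimated correlation). Neutrophil markers fell in 8 of 13 cases (11 adjusted over the list alone), with the collagenase Mmp8 at -2.48 (camera adjusted p = 0.000149; adjusted p = 0.509 with an estimated correlation). Of 24 monocyte and macrophage markers 1 rose and 5 fell, including Cd68 at -0.75, and the list was not called (camera adjusted p = 0.372). Interferon response genes fell in 9 of 32 cases (9 adjusted over the list alone), including Ifit3 at -2.02 and Gbp2 at -1.14 (camera adjusted p = 0.000252; adjusted p = 0.509 with an estimated correlation). The inflammasome, pyroptosis and necroptosis list had 4 of 16 members lower (5 adjusted over the list alone), including the necroptosis kinase Ripk3 at -1.17 (camera adjusted p = 0.00418; adjusted p = 0.284 with an estimated correlation). Of 18 lymphocyte markers 0 passed in edgeR or DESeq2 and 0 adjusted over the list alone (4 were lower at an unadjusted p under 0.05), while the list median was -0.56 (camera adjusted p = 0.00226; adjusted p = 0.334 with an estimated correlation).

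Immediate early genes, the first transcription factors induced by stress signals, fell in 11 of 22 cases at 4 h (14 adjusted over the list alone), with a median of -0.99 (camera adjusted p = 3.29e-06; adjusted p = 0.334 with an estimated correlation). The log2 fold change was -2.16 ± 0.23 for Egr3, -1.49 ± 0.16 for Myc and -1.73 ± 0.39 for Egr1, the last from 566.5 ± 154 to 171.3 ± 29.4 CPM (edgeR adjusted p = 0.00919, 0.00919 and 0.0282). Genes of feedback on the ERK pathway fell in 7 of 16 cases and rose in 1 (9 and 1 adjusted over the list alone), with the receptor Epha2 at -1.61 and the inhibitor Spry4 at -1.33 (camera adjusted p = 0.00145; adjusted p = 0.284 with an estimated correlation). Cardiac stress genes fell in 10 of 15 cases (11 adjusted over the list alone), with a median of -1.16 (camera adjusted p = 2.09e-05; adjusted p = 0.334 with an estimated correlation). They included Xirp1 at -1.43 ± 0.15 and Xirp2 at -1.69 ± 0.23, which encode actin-binding proteins of the intercalated disc, and Nppb at -1.67 ± 0.33, the gene of B-type natriuretic peptide (edgeR adjusted p = 0.00919, 0.0107 and 0.0203). Heat shock genes fell in 8 of 15 cases (11 adjusted over the list alone), with the chaperones Hsph1 at -1.18 and Dnaja1 at -1.08 (camera adjusted p = 2.69e-05; adjusted p = 0.372 with an estimated correlation). Genes of the unfolded protein and integrated stress responses fell in 13 of 26 cases and rose in 1 (16 and 2 adjusted over the list alone), among them Asns, asparagine synthetase, at -1.27 (camera adjusted p = 2.73e-05; adjusted p = 0.334 with an estimated correlation). Apoptosis and p53 target genes fell in 9 of 25 cases and rose in 2 (12 and 2 adjusted over the list alone), with Casp8, the initiator caspase of death receptors, at -1.29 (camera adjusted p = 0.00959; adjusted p = 0.284 with an estimated correlation). NRF2 targets of the antioxidant response fell in 4 of 17 cases (4 adjusted over the list alone), with Srxn1 at -1.08 (camera adjusted p = 0.0272; adjusted p = 0.749 with an estimated correlation).

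Among matrix genes at 4 h, Ctgf, a connective tissue growth factor, fell by 2.54 ± 0.28 from 1997 ± 419 to 343 ± 140 CPM (edgeR adjusted p = 0.00919). The matrix proteases and their inhibitors fell in 10 of 22 cases and rose in 1 (12 and 1 adjusted over the list alone), with Timp1 at -1.40 (camera adjusted p = 9.01e-05; adjusted p = 0.334 with an estimated correlation). Extracellular matrix and fibrosis genes fell in 9 of 32 cases (17 adjusted over the list alone), with the list median at -0.45 (camera adjusted p = 0.000885; adjusted p = 0.377 with an estimated correlation). Blood markers of infarction and heart failure fell in 11 of 23 cases (13 adjusted over the list alone), including Thbs1 at -1.77 and Fstl3 at -1.42 (camera adjusted p = 6.48e-06; adjusted p = 0.311 with an estimated correlation). Of 25 fatty acid oxidation genes 1 rose, Cpt1a, and 24 did not pass, with 1 adjusted over the list alone (camera adjusted p = 0.0481; adjusted p = 0.334 with an estimated correlation). Of 28 oxidative phosphorylation genes 0 passed in edgeR or DESeq2, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.937). Ehhadh, a peroxisomal fatty acid oxidation enzyme, rose by 1.88, Ddit4, an inhibitor of mTORC1, by 1.57, and Nebl, an actin-binding protein of the Z-disc, by 1.33. Other transcripts that rose included Lvrn (2.60), Sned1 (2.49), Klhl38 (2.41), Cyp1b1 (2.38) and Trh (2.12). Vcam1, an endothelial adhesion molecule, rose by 0.80 ± 0.14 (edgeR adjusted p = 0.0145), whereas Icam1 fell, at -0.88. Ccl2 (-2.21 ± 0.66, edgeR adjusted p = 0.0647), Il6 (-1.05 ± 0.73, adjusted p = 0.364) and Fos (-0.86 ± 0.29, adjusted p = 0.0807) did not pass. Neither did Fosb (-0.32 ± 0.74, edgeR adjusted p = 0.806) and Nppa (-0.56 ± 0.31, adjusted p = 0.242).

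The 4 h gene count depended on single libraries, being 112 without BT2 replicate 2, 279 without vehicle replicate 2, 1335 without BT2 replicate 1 and 2796 without vehicle replicate 1, and 621 when the 4 h libraries were fitted alone. Of the 71 named genes called, 14 passed in each of the 4 fits without 1 library: Csf2, Tnfsf18, Ctgf, Osm, Egr3, Ifit3, Myc, Xirp1, Hsph1, Gbp2, P4ha1, Cpt1a, Sned1 and Lvrn. With upper quartile factors 1298 genes were higher and 1244 lower. Camera called 17 of 34 lists, 1 higher and 16 lower, and 0 with an estimated correlation. With the replicate number as a block it called 0 higher and 16 lower, so the fatty acid oxidation list lost its call. Without vehicle replicate 1 the camera adjusted p was 0.0676 for matrix, 0.182 for fatty acid oxidation and 0.124 for interferon response genes. It was 0.293 for NRF2 targets without vehicle replicate 2, and 0.1 for NRF2 targets and 0.165 for fatty acid oxidation genes without BT2 replicate 1.

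**Figure D1:**
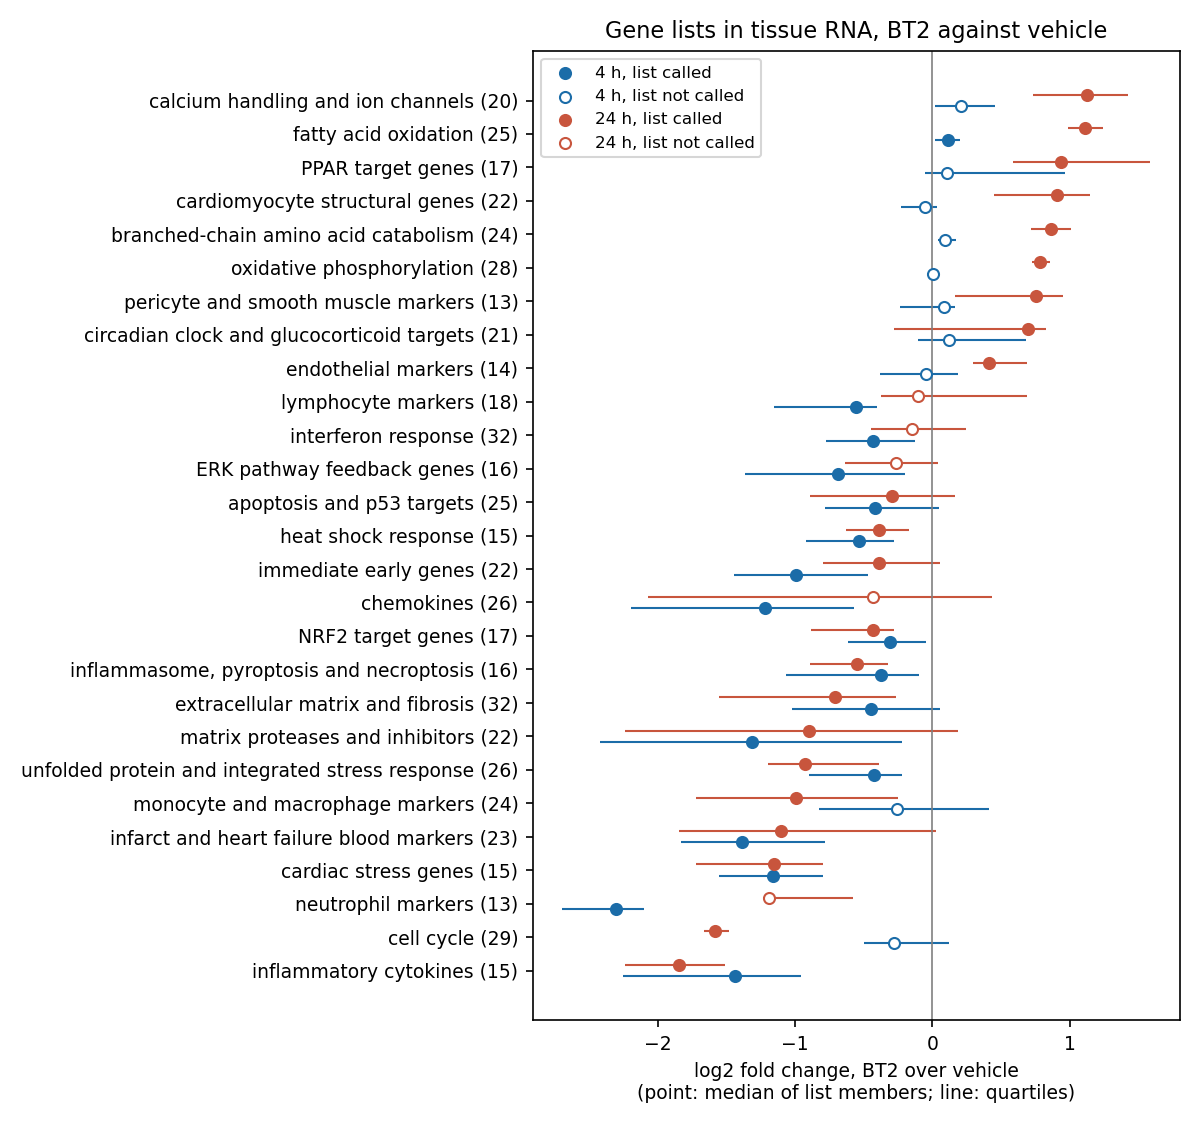
Median log2 fold change of BT2 against vehicle in tissue RNA at 4 h and 24 h for the gene lists called at either time (filled points, called by camera with the preset correlation; with an estimated correlation it called 0), with the quartiles of the members as lines and the number of tested members in brackets. The fatty acid oxidation median lies at 0.11 at 4 h and 1.11 at 24 h, and the cell cycle median at -0.28 and -1.58.

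**Figure D2:**
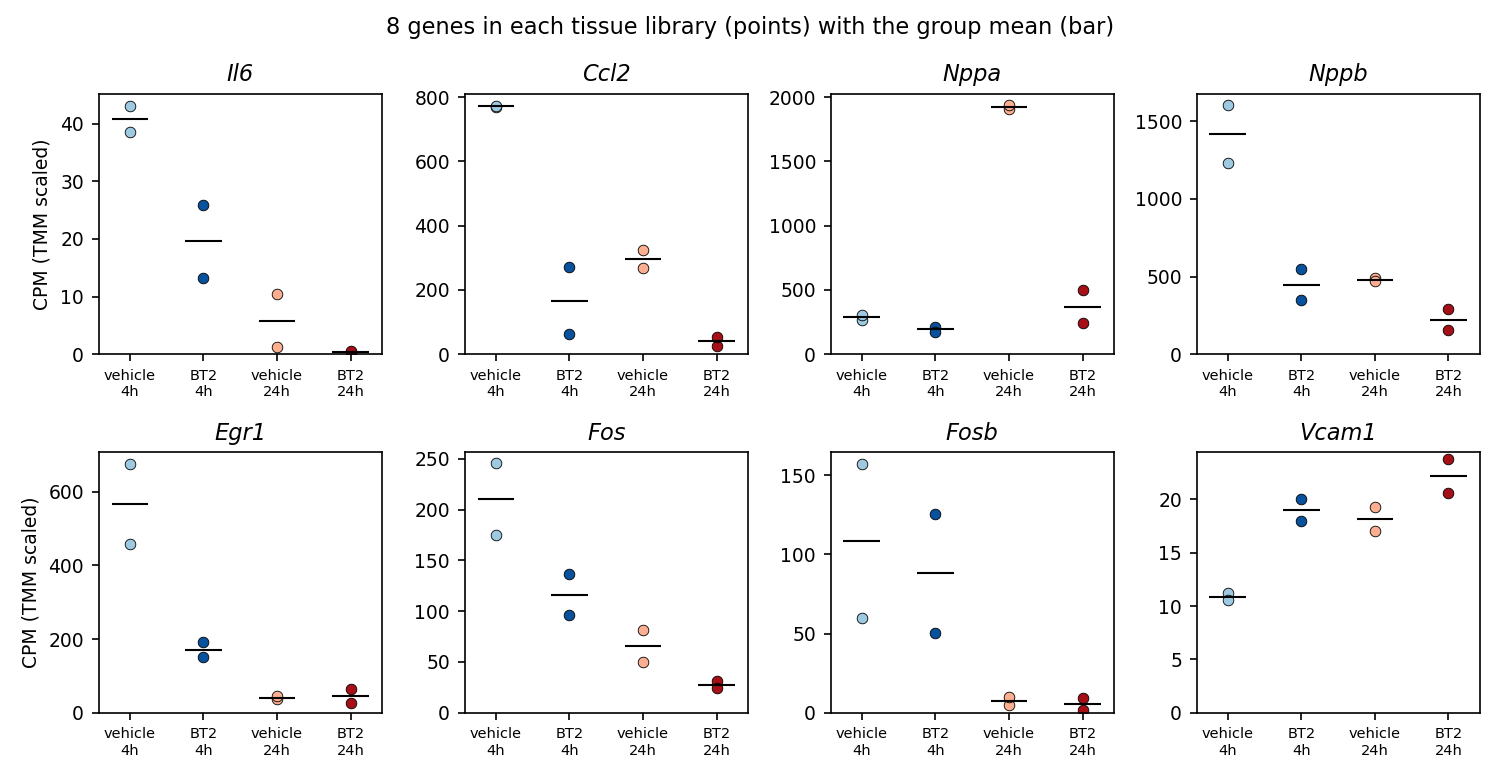
CPM of 8 genes chosen in advance, with 1 point per tissue library (2 per group) and the group mean as a horizontal line. Nppa averages 1925 CPM in vehicle and 369.7 CPM with BT2 at 24 h, and Egr1 566.5 and 171.3 CPM at 4 h.

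The comparison at 24 h asked the same question one day after injury. Transcripts of mitochondrial energy metabolism and of the contractile and calcium handling machinery were higher with BT2, and cell cycle, matrix, macrophage and stress transcripts were lower. Fabp3, the fatty acid-binding protein of heart muscle, rose by 1.59 ± 0.14 (edgeR adjusted p = 0.000406), from 620.5 ± 24.9 to 1865 ± 189 CPM. Nppa, the gene of atrial natriuretic peptide, fell by 2.38 ± 0.32 (edgeR adjusted p = 0.00168), from 1925 ± 21.0 to 369.7 ± 184 CPM. In all, edgeR called 6016 of 15216 genes, 2873 higher and 3143 lower with BT2.

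Of 25 fatty acid oxidation genes 23 rose at 24 h (24 adjusted over the list alone) and 0 fell, with a median of 1.11 (camera adjusted p = 7.99e-13; adjusted p = 0.0865 with an estimated correlation). Acsl1, which activates long-chain fatty acids, rose by 1.58 ± 0.11, and Slc25a20, the carnitine-acylcarnitine carrier, by 1.31 ± 0.10 (edgeR adjusted p = 0.000331 for both). All 28 oxidative phosphorylation genes rose (28 adjusted over the list alone), with a median of 0.78, including the complex I subunits Ndufs3 at 0.99 and Ndufs7 at 0.94 (camera adjusted p = 6.87e-12; adjusted p = 0.353 with an estimated correlation). Of 24 genes of branched-chain amino acid catabolism 23 rose and 1 fell (23 and 1 adjusted over the list alone), with Hibch of valine breakdown at 1.04 and Mccc2 of leucine breakdown at 0.97 (camera adjusted p = 1.69e-08; adjusted p = 0.31 with an estimated correlation). PPAR targets rose in 10 of 17 cases (10 adjusted over the list alone), Fabp3 and Slc25a20 among them (camera adjusted p = 0.000511; adjusted p = 0.31 with an estimated correlation). Calcium handling and ion channel genes rose in 16 of 20 cases (16 adjusted over the list alone), with triadin (Trdn) at 1.30 ± 0.12 and the sarcoplasmic calcium-binding protein Hrc at 1.61 ± 0.13 (camera adjusted p = 4.43e-08; adjusted p = 0.31 with an estimated correlation). Cardiomyocyte structural genes rose in 16 of 22 cases and fell in 2 (17 and 2 adjusted over the list alone), with the M-band protein Myom2 at 1.58 from 1153 ± 30.4 to 3449 ± 363 CPM (camera adjusted p = 3.92e-06; adjusted p = 0.394 with an estimated correlation). Circadian clock and glucocorticoid target genes rose in 11 of 21 cases and fell in 2 (12 and 4 adjusted over the list alone), with Per3 at 1.26 (camera adjusted p = 0.0366; adjusted p = 0.353 with an estimated correlation). Of 21 glycolysis genes 6 rose and 4 fell, with the muscle forms Pfkm and Eno3 at 1.42 and 1.16 and the list not called (camera adjusted p = 0.949).

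Markers of other cell types moved at 24 h as well. Endothelial markers rose in 7 of 14 cases (8 adjusted over the list alone), with the water channel Aqp1 at 0.76 (camera adjusted p = 0.00685; adjusted p = 0.394 with an estimated correlation). Pericyte and smooth muscle markers rose in 7 of 13 cases and fell in 2 (7 and 2 adjusted over the list alone), with the myosin kinase Mylk at 0.95 (camera adjusted p = 0.0366; adjusted p = 0.526 with an estimated correlation). Fibroblast markers rose in 6 of 13 cases and fell in 2, including Dcn, the proteoglycan decorin, at 1.64 ± 0.17, and the list was not called (camera adjusted p = 0.0581). Monocyte and macrophage markers fell in 15 of 24 cases and rose in 1 (15 and 1 adjusted over the list alone), with a median of -0.99 (camera adjusted p = 0.000873; adjusted p = 0.31 with an estimated correlation). Those that fell included Gpnmb, a glycoprotein of lipid-laden macrophages, at -2.46 ± 0.24 from 1456 ± 401 to 265 ± 40.4 CPM, and the lysosomal protein Cd68 at -1.71 ± 0.14, and the member that rose was the complement gene C1qa at 0.76. Of 13 neutrophil markers 0 passed in edgeR and 0 adjusted over the list alone, with 4 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and a median of -1.19 (camera adjusted p = 0.0832). Among 18 lymphocyte markers Cd8a had -2.43 and Cd4 had 0.75, both past the threshold, in a list that was not called (camera adjusted p = 0.996). In nuclei at 24 h 41.9% of the UMIs of Cd4 lay in monocyte or macrophage-like nuclei. For Cd8a 16.7% lay in lymphocyte-like nuclei, so these values need not come from T cells.

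All 29 cell cycle genes fell at 24 h (29 adjusted over the list alone), with a median of -1.58 (camera adjusted p = 4.37e-10; adjusted p = 0.353 with an estimated correlation). They included the replication helicase subunit Mcm5 at -1.65 ± 0.16 and the transcription factor E2f1 at -1.52 ± 0.18. Extracellular matrix and fibrosis genes fell in 18 of 32 cases (18 adjusted over the list alone) and 0 rose, with a median of -0.71 (camera adjusted p = 4.75e-06; adjusted p = 0.31 with an estimated correlation). Ltbp2, a latent TGF-beta binding protein, fell by 2.98 ± 0.21, and the growth factor Tgfb2 had -2.27 ± 0.16 (edgeR adjusted p = 0.000331 for both). Matrix proteases and inhibitors fell in 12 of 22 cases and rose in 4 (12 and 5 adjusted over the list alone), with the macrophage elastase Mmp12 at -3.60 ± 0.44 and Mmp2 at 1.31 (camera adjusted p = 0.0366; adjusted p = 0.499 with an estimated correlation). Cytokines fell in 10 of 15 cases (10 lower and 1 higher adjusted over the list alone), with Osm at -1.85 and Il18 at -1.59 (camera adjusted p = 0.000357; adjusted p = 0.31 with an estimated correlation). Of 26 chemokines 4 rose and 9 fell, with the monocyte attractant Ccl12 at -3.15 and Ccl5 at 0.69, and the list was not called (camera adjusted p = 0.224). Cardiac stress genes fell in 11 of 15 cases (13 lower and 1 higher adjusted over the list alone), with Xirp2 at -2.12 (camera adjusted p = 0.000145; adjusted p = 0.353 with an estimated correlation). Blood markers of infarction and heart failure fell in 11 of 23 cases and rose in 2 (11 and 2 adjusted over the list alone), with Thbs1 at -2.25 and Fstl3 at -2.20 (camera adjusted p = 0.0045; adjusted p = 0.353 with an estimated correlation).

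Genes of the unfolded protein and integrated stress responses fell in 19 of 26 cases and rose in 3 (19 and 3 adjusted over the list alone), with the endoplasmic reticulum proteins Creld2 at -1.79 and Manf at -1.12 (camera adjusted p = 1.58e-05; adjusted p = 0.31 with an estimated correlation). Heat shock genes fell in 7 of 15 cases and rose in 2 (7 and 2 adjusted over the list alone), with Hspb1 at -1.73 (camera adjusted p = 0.0366; adjusted p = 0.526 with an estimated correlation). Immediate early genes fell in 8 of 22 cases (8 adjusted over the list alone), with Myc at -1.70 (camera adjusted p = 0.0366; adjusted p = 0.526 with an estimated correlation). NRF2 targets fell in 7 of 17 cases and rose in 2 (7 and 2 adjusted over the list alone), with Gclc at -0.89 (camera adjusted p = 0.0366; adjusted p = 0.579 with an estimated correlation). Inflammasome genes fell in 8 of 16 cases and rose in 2 (9 and 2 adjusted over the list alone), with Ripk3 at -1.69 (camera adjusted p = 0.0366; adjusted p = 0.31 with an estimated correlation). Apoptosis and p53 targets fell in 9 of 25 cases and rose in 2 (11 and 2 adjusted over the list alone), with Bax at -0.98 and Bak1 at -0.89 (camera adjusted p = 0.0366; adjusted p = 0.31 with an estimated correlation). The genes with the highest log2 fold changes included Aox1, an aldehyde oxidase (3.81 ± 0.38), Enpp2, the enzyme that makes lysophosphatidic acid (3.03 ± 0.16), and Scara5, a ferritin receptor (2.89 ± 0.34). Egr1 (0.16 ± 0.39, edgeR adjusted p = 0.764), Fosb (-0.43 ± 0.86, adjusted p = 0.721) and Vcam1 (0.29 ± 0.13, adjusted p = 0.117) did not pass. Fos fell by 1.27 ± 0.29 (edgeR adjusted p = 0.0128).

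The 24 h gene count was 3469 without vehicle replicate 1, 3072 without vehicle replicate 2 and 2982 without BT2 replicate 1. Il6 fell by 3.71 ± 1.10, Ccl2 by 2.85 ± 0.68 and Nppb by 1.11 ± 0.33 (edgeR adjusted p = 0.0362, 0.0168 and 0.03). With Fos and Ccl5 they were among 11 of 80 named calls that ended in a fit without 1 library. The highest adjusted p was 0.173 for Il6, 0.107 for Ccl2 and 0.0537 for Ccl5 (each without BT2 replicate 1), 0.108 for Nppb (without vehicle replicate 1) and 0.0728 for Fos (without BT2 replicate 2). Camera called 22 of 34 lists, 9 higher and 13 lower, and 0 with an estimated correlation. Its adjusted p was 0.085 for matrix proteases without vehicle replicate 1, 0.101 for NRF2 targets without BT2 replicate 1, and 0.48 for immediate early and 0.134 for heat shock genes without BT2 replicate 2. For circadian genes it was 0.0731 without vehicle replicate 2 and 0.0531 without BT2 replicate 1. With an estimated correlation camera called 0 lists at 4 h, at 24 h and for time in vehicle. At an unadjusted p under 0.05 it had 4, 2 and 2 lists, and fry called 14, 22 and 22.

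The next question was whether the BT2 effect differed between the times. Mitochondrial genes were among those that differed, and the 24 h effect exceeded the 4 h effect for 23 of 28 oxidative phosphorylation genes (28 adjusted over the list alone) and 19 of 25 fatty acid oxidation genes (21 adjusted over the list alone). Cell cycle genes differed the other way in 8 of 29 cases (13 adjusted over the list alone). Enpp2 had 0.39 at 4 h and 3.03 at 24 h, a difference of 2.64 ± 0.21, and Gsn, the actin-severing protein gelsolin, had -0.15 and 1.73 (edgeR adjusted p = 0.0122 for both differences). Gbp1, an interferon-induced GTPase, had -0.66 and 1.35, and Sod3, the extracellular superoxide dismutase, 0.45 and 1.93 (edgeR adjusted p = 0.0122 for both). Folr2, a folate receptor of resident macrophages, had 0.86 at 4 h and -0.84 at 24 h, and Npl, N-acetylneuraminate lyase, 0.90 and -1.02 (edgeR adjusted p = 0.0144 and 0.0157). The test of the difference called 1087 genes, 718 with the higher and 369 with the lower value at 24 h. Of the genes called at both times, 515 were higher and 934 lower at both, against 191.6 and 305.7 expected by chance, and 25 and 31 went opposite ways. Across genes, which are not independent replicates, the effects at 4 h and 24 h correlated at r = 0.468 (Spearman 0.490). The edgeR count of the difference was 0 without vehicle 24 h replicate 2 (2854 genes at an unadjusted p under 0.05), and DESeq2 called 1570 genes on all libraries. In that edgeR fit the adjusted p was 0.0547 for Enpp2 and Gbp1, 0.0554 for Gsn and Sod3 and 0.0661 for Folr2 and Npl. It was 22 without BT2 24 h replicate 1, 48 without vehicle 24 h replicate 1, 102 and 296 without BT2 4 h replicates 2 and 1, and 363 without vehicle 4 h replicate 2.

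The course of injury without the compound was read from vehicle at 24 h against 4 h. Macrophage, cell cycle and matrix transcripts rose with time, and mitochondrial, contractile and immediate early transcripts fell. Spp1, the macrophage and matrix protein osteopontin, rose by 7.37 ± 0.49 (edgeR adjusted p = 9.2e-05), from 23.2 ± 4.49 to 3800 ± 1359 CPM. Gpnmb rose by 5.37 ± 0.28 and Mmp12 by 6.45 ± 0.60 (edgeR adjusted p = 6.6e-05 and 0.000366). Myh6, the fast cardiac myosin heavy chain, fell by 2.74 ± 0.18 (edgeR adjusted p = 8.46e-05). Of 29 cell cycle genes 29 rose (29 adjusted over the list alone), with E2f1 at 3.78 (camera adjusted p = 6e-12; adjusted p = 0.38 with an estimated correlation). Of 24 monocyte and macrophage markers 17 rose (17 adjusted over the list alone; camera adjusted p = 5.53e-07; adjusted p = 0.369 with an estimated correlation). Extracellular matrix genes rose in 21 of 32 cases and fell in 3 (21 and 3 adjusted over the list alone), with the crosslinking enzyme Loxl1 at 1.83 (camera adjusted p = 0.000617; adjusted p = 0.38 with an estimated correlation). Unfolded protein and integrated stress response genes rose in 15 of 26 cases and fell in 6 (15 and 6 adjusted over the list alone), with Pdia4 at 2.42 (camera adjusted p = 0.0097; adjusted p = 0.487 with an estimated correlation). In all, edgeR called 7162 genes, 3545 higher and 3617 lower at 24 h, and 4629 without vehicle replicate 2 at 24 h. Under upper quartile factors 4307 were higher and 3018 lower.

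Mitochondrial lists fell with time in vehicle. All 28 oxidative phosphorylation genes fell (28 adjusted over the list alone; camera adjusted p = 1.64e-13; adjusted p = 0.38 with an estimated correlation), with Ndufs3 at -1.21. Fatty acid oxidation genes fell in 21 of 25 cases and rose in 1 (22 and 1 adjusted over the list alone; camera adjusted p = 4.41e-10; adjusted p = 0.147 with an estimated correlation), with Acsl1 at -1.83. Branched-chain amino acid genes fell in 22 of 24 cases (23 adjusted over the list alone; camera adjusted p = 3.47e-09; adjusted p = 0.38 with an estimated correlation). Cardiomyocyte structural genes fell in 20 of 22 cases and calcium handling genes in 14 of 20 (20 and 14 adjusted over the list alone; camera adjusted p = 2.35e-09 and 8.65e-06; adjusted p = 0.38 for both with an estimated correlation). Immediate early genes fell in 19 of 22 cases (21 adjusted over the list alone), with Egr3 at -3.54 and Nr4a3 at -2.90 (camera adjusted p = 3.74e-08; adjusted p = 0.38 with an estimated correlation). Neutrophil markers fell in 9 of 13 cases (10 adjusted over the list alone), with Mmp8 at -4.14 (camera adjusted p = 0.00635; adjusted p = 0.562 with an estimated correlation). Heat shock genes fell in 13 of 15 cases (13 adjusted over the list alone), with Hspa1a at -5.83, whose near-identical copy makes its counts uncertain (camera adjusted p = 0.000132; adjusted p = 0.395 with an estimated correlation). Endothelial markers fell in 9 of 14 cases and rose in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00635; adjusted p = 0.44 with an estimated correlation). Nppa rose by 2.75 ± 0.32 (edgeR adjusted p = 0.000502), in a cardiac stress list with 7 of 15 members lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.0448; adjusted p = 0.573 with an estimated correlation). Without vehicle 4 h replicate 2 the cardiac stress list had a camera adjusted p of 0.13, and 0.0522 without vehicle 24 h replicate 1. Camera called 20 of 34 lists, 4 higher and 16 lower at 24 h, and 0 with an estimated correlation. Under upper quartile factors the median log2 fold change of all genes was 0.118 in this comparison and 0.108 for time with BT2, against 0.006 and 0.02 under TMM.

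The course from 4 h to 24 h was also read with BT2, where Spp1 rose by 5.35 ± 0.45 and Gpnmb by 3.73 ± 0.26 (edgeR adjusted p = 0.00161 and 0.000871). Reg3b, a regenerating islet-derived lectin, rose by 4.32 ± 0.19 (edgeR adjusted p = 0.000173), and C3ar1, the receptor of complement fragment C3a, by 2.81. The log2 fold change was -2.93 for Thbs1, -3.43 for the stress transcription factor Atf3 and -3.10 for Nr4a3. Myh6 fell by 1.68 ± 0.17 (edgeR adjusted p = 0.00184). Immediate early genes fell in 15 of 22 cases (17 adjusted over the list alone), cell cycle genes rose in 17 of 29 (21 adjusted over the list alone), and oxidative phosphorylation genes fell in 14 of 28 (24 adjusted over the list alone). The edgeR count was 3548, with 1782 higher and 1766 lower, and upper quartile factors gave 2296 and 1265. It was 1025 without BT2 24 h replicate 2, 1114 without BT2 4 h replicate 1, 1875 without BT2 24 h replicate 1 and 2046 without BT2 4 h replicate 2.

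The nuclear libraries asked which cell classes were present at 24 h and how their transcripts compared between vehicle and BT2, with 1 library per group and so no test between them. Neutrophil-like nuclei made up 5.91% of vehicle and 2.3% of BT2 nuclei, a ratio of 0.388 (95% interval 0.334 to 0.451, counting error only). Monocyte or macrophage-like nuclei made up 20.97% and 14.16% (ratio 0.675, 0.632 to 0.721), and fibroblast-like nuclei 13.57% and 27.41% (ratio 2.02, 1.90 to 2.15). These classes joined clusters that moved unequally. Of the 3 monocyte or macrophage clusters, the one led by Spp1 and Gpnmb went from 14.57% to 8.34%, another from 3.46% to 2.18% and the last from 2.94% to 3.64%. The fibroblast cluster led by Hmcn2, Dcn and Scara5 went from 4.90% to 15.98% (ratio 3.26, 2.96 to 3.60), and the cluster led by Ltbp2, Tnc and Postn from 8.67% to 11.43% (ratio 1.32, 1.21 to 1.44). Schwann or neuronal-like nuclei, 87 in vehicle and 266 with BT2, had a ratio of 3.37 (2.63 to 4.34). Smooth muscle-like nuclei had 2.06 (1.61 to 2.65) and dendritic-like nuclei 0.483 (0.377 to 0.617). No cluster got the dendritic name with doublets kept or under limits of 1000 UMIs and 1% mitochondrial UMIs. Cardiomyocyte-like nuclei made up 7.46% and 7.76% (ratio 1.04, 0.943 to 1.15), and blood endothelial-like nuclei 20.84% and 19.10% (ratio 0.917, 0.863 to 0.973). As shares are parts of a whole, the larger fibroblast-like share by itself lowers those of the other classes. A ratio below 1, such as that of blood endothelial-like nuclei, thus need not mean fewer nuclei of that class in the tissue. Of the 3 blood endothelial clusters the larger ones had ratios of 0.822 and 0.887, and the smallest, with 60 nuclei in vehicle and 170 with BT2, 3.12 (2.31 to 4.26). Pericyte-like nuclei had a ratio of 1.19 (1.07 to 1.32), which turned to 0.984 (0.910 to 1.06) at Leiden resolution 0.3. Lymphocyte-like nuclei had 1.004 (0.841 to 1.20), and 0.649 (0.452 to 0.924) under limits of 1000 UMIs and 1% mitochondrial UMIs. Nuclei left without a class name made up 18.34% of vehicle and 13.45% of BT2 nuclei, and the depth differed, with medians of 2465 and 2157 UMIs per nucleus.

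**Figure D3:**
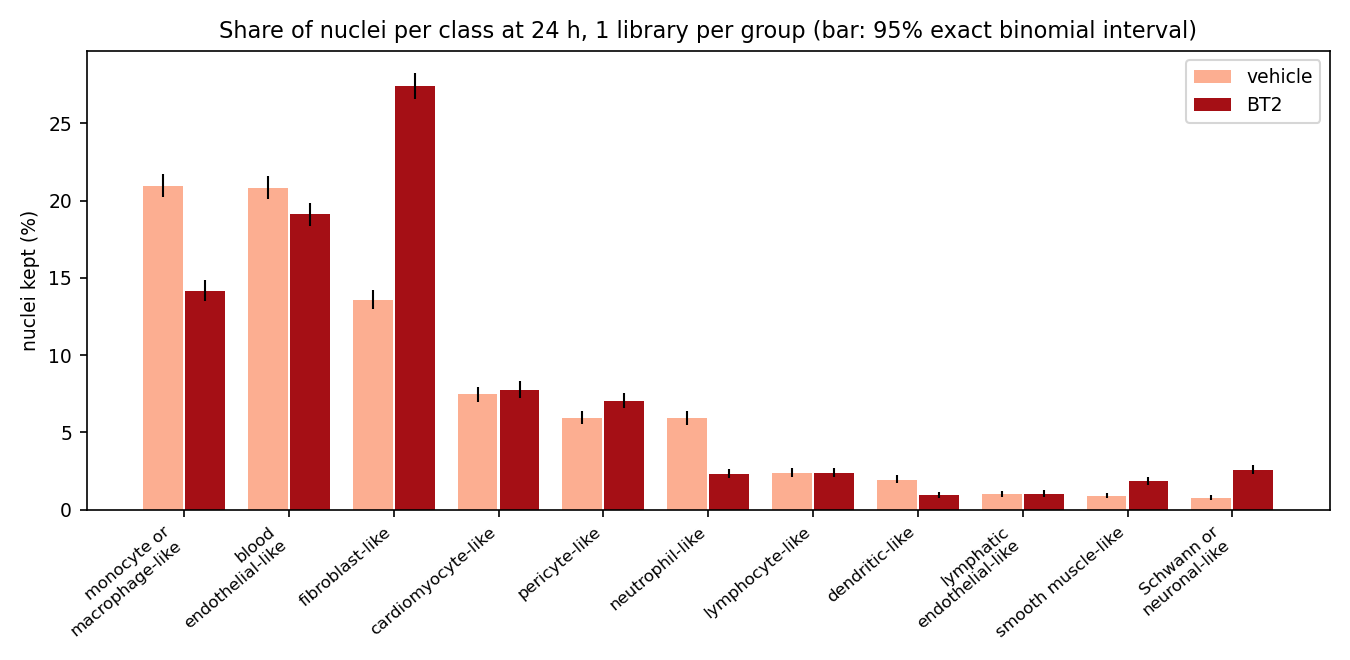
Percent of nuclei in each class in the vehicle and BT2 libraries at 24 h, with exact binomial 95% intervals as bars (1 library per group). Fibroblast-like nuclei lie at 13.57% in vehicle and 27.41% with BT2, and neutrophil-like nuclei at 5.91% and 2.3%.

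Within cardiomyocyte-like nuclei (848 in vehicle, 801 with BT2, median 6378 and 3480 UMIs), Xirp2 had a CPM ratio of BT2 over vehicle of 2.15 (95% interval 2.12 to 2.19). Nppa had 1.49 (1.36 to 1.65) and Nppb 1.10 (0.996 to 1.22). Cdo1, cysteine dioxygenase, had 0.0551 (0.0111 to 0.167). Fatty acid oxidation genes had a median log2 ratio of -0.45 with 22 of 25 members lower, at percentile 0 among 10000 matched random lists, with Acadl at a ratio of 0.592 and Acsl1 at 0.671. Oxidative phosphorylation genes had a median of -0.31 (24 of 29 lower, percentile 0.18) and branched-chain amino acid genes -0.28 (21 of 24 lower, percentile 0.49). Structural genes had 0.11 (percentile 98.8), cardiac stress genes 0.13 (percentile 98.1) and interferon response genes -0.58 (percentile 0.05). Markers of other cells were read in these nuclei too, with macrophage markers at a median of -1.18 and fibroblast markers at 0.49, so RNA from other cells is not excluded. After thinning nuclei of both libraries to 1000 UMIs the fatty acid oxidation median was -0.34 (percentile 0.5) and the oxidative phosphorylation median -0.26 (percentile 6.52). The interferon median turned to 0.0441 (percentile 70.08), with 6 members left of 21.

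Within blood endothelial-like nuclei, heat shock genes had a median log2 ratio of 0.88 (13 of 15 higher, percentile 100), genes of the unfolded protein response 0.32 (20 of 22 higher, percentile 100) and immediate early genes 0.39 (17 of 20 higher, percentile 99.99). Interferon response genes had -0.49 (24 of 28 lower, percentile 0) with Mx2 at a ratio of 0.247 (0.149 to 0.394), and cell cycle genes -0.38 (percentile 0.07). Vcam1 had a ratio of 0.815 (0.698 to 0.95) and Il6 2.43 (1.54 to 3.90), and pericyte and smooth muscle markers a median of 1.03. In the 3 clusters of this class Vcam1 had 0.823 (0.690 to 0.979), 1.63 (0.722 to 3.77) and 0.374 (0.255 to 0.545). The list medians in the first and second of them were 0.31 and 1.15 for heat shock, 0.25 and 0.36 for immediate early and -0.27 and -0.65 for interferon response genes. They were 0.11 and 0.49 for the unfolded protein response and -0.30 and -0.38 for cell cycle genes, where the values of the first cluster lay within the 95% range of random lists. In fibroblast-like nuclei Fosb had a ratio of 0.303 (0.221 to 0.412), Fos 0.536 (0.447 to 0.643), Il6 2.55 (1.58 to 4.28) and Ccl2 1.11 (0.986 to 1.26). The Ltbp2 and Hmcn2 clusters made up 63.9% and 36.1% of the class in vehicle and 41.7% and 58.3% with BT2, so ratios over the class may carry a change of mix. By cluster, Fosb had 0.372 and 0.197, Fos 0.555 and 0.481, and Ccl2 1.20 and 1.67. Il6 had 4.04 (2.27 to 7.74) in the Ltbp2 cluster and 0.669 (0.245 to 1.91) in the Hmcn2 cluster. The serotonin receptor gene Htr2a had 6.68 in the class (6.92 and 8.66 by cluster) and Plscr1 0.266 (0.25 in both). Interferon response genes had a median of -0.29 (percentile 0.63), and -0.0761 (percentile 54.63) after thinning. By cluster the medians were -0.47 and, within the 95% range of random lists, -0.21 (percentile 7.16). Endothelial markers had 0.42 in the same nuclei. Macrophage markers had -0.44, which turned to 0.0349 without the highest 8% of Scrublet scores.

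Within monocyte or macrophage-like nuclei, Milr1, an inhibitory immunoglobulin-like receptor, had a ratio of 0.168 (0.119 to 0.233) and Adamts13 0.0607 (0.022 to 0.134). Fos had 0.550 (0.445 to 0.676) and Ccl2 1.34 (1.10 to 1.62) there. Interferon response genes had a median of -0.56 (23 of 27 lower, percentile 0), NRF2 targets -0.26 (percentile 1.22) and hypoxia genes 0.28, beside fibroblast markers at 0.96 and endothelial markers at 0.75. In the 3 clusters the interferon medians were -0.90, -0.55 and -0.50. The NRF2 medians were -0.11, -0.10 and -0.22 and the hypoxia medians 0.15, 0.10 and 0.06, all within the 95% range of the random lists. Within neutrophil-like nuclei, Usp18 had a ratio of 0.0765 (0.0205 to 0.2) and Cxcl2 0.144, interferon response genes a median of -0.98 (15 of 17 lower, percentile 0) and heat shock genes 1.06, beside endothelial markers at 0.66. Within pericyte-like nuclei, Il6 had 2.44 (1.76 to 3.42), Ddx60 0.137, and interferon response genes a median of -0.88 (12 of 15 lower, percentile 0). Endothelial markers had 0.68, fibroblast markers 0.58 and macrophage markers -0.44 there. Lymphocyte-like nuclei had Cd69 at 0.365, beside endothelial markers at 1.12 (11 of 11 higher, percentile 100), so RNA from other cells is not excluded in either class. Smooth muscle-like nuclei had Hgf at 0.393 and lymphatic endothelial-like nuclei Reep1 at 2.93.

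The 8 genes chosen in advance had further ratios in nuclei, many from few UMIs. Fos had 0.714 (0.520 to 0.973) in cardiomyocyte-like, 0.803 (0.641 to 1.003) in blood endothelial-like, 0.848 (0.484 to 1.43) in neutrophil-like and 0.647 (0.387 to 1.07) in pericyte-like nuclei. In smooth muscle-like nuclei it had 1.38 (0.870 to 2.24), and 0.105 (0.0121 to 0.421) in lymphatic endothelial-like nuclei. Fosb had 0.150 (0.0293 to 0.484) in cardiomyocyte-like and 0.131 (0.0148 to 0.534) in lymphatic endothelial-like nuclei. Its intervals included 1 in blood endothelial-like (0.765), macrophage-like (0.621), pericyte-like (0.679) and smooth muscle-like nuclei (0.484). Ccl2 had 0.570 (0.332 to 0.949) in cardiomyocyte-like and 4.11 (1.25 to 17.5) in lymphatic endothelial-like nuclei. Elsewhere its intervals included 1, with 1.29 in blood endothelial-like, 0.789 in neutrophil-like, 1.26 in pericyte-like and 0.376 in smooth muscle-like nuclei. Vcam1 had 1.66 (1.11 to 2.53) in fibroblast-like nuclei, 0.888 (0.510 to 1.56) in their Ltbp2 cluster and 3.19 (1.57 to 7.31) in their Hmcn2 cluster. Its intervals included 1 in cardiomyocyte-like (0.774) and macrophage-like nuclei (0.967). The intervals of Egr1 included 1 in each class, with 1.94 in blood endothelial-like, 0.726 in cardiomyocyte-like, 0.882 in fibroblast-like, 0.272 in macrophage-like and 1.47 in pericyte-like nuclei. Il6 had 1.13 in cardiomyocyte-like and 0.847 in smooth muscle-like nuclei, with intervals that included 1. Nppa had 0.364 (0.152 to 0.787) in blood endothelial-like nuclei, from 30 UMIs in vehicle and 9 with BT2. Levels there were 2.27% (Nppa) and 1.95% (Nppb) of those in cardiomyocyte-like nuclei, so RNA from other cells is not excluded. The Nppa intervals included 1 in fibroblast-like (0.599), macrophage-like (0.875) and neutrophil-like nuclei (0.565). Nppb had such intervals in blood endothelial-like (1.21), fibroblast-like (1.04) and macrophage-like nuclei (0.476).

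The last question was whether tissue and nuclei gave like differences between BT2 and vehicle at 24 h. Enpp2 (ratio 3.63, 3.16 to 4.18), Dcn (2.31, 2.21 to 2.41), Aox1 (4.15) and Scara5 (2.66) were higher with BT2 in the summed nuclei, as in tissue. Gpnmb (0.480, 0.466 to 0.495), Mmp12 (0.343), Milr1 (0.145), Cd68 (0.522) and Il18 (0.457) were lower in both. Ltbp2 (1.39), Nppa (1.25, 1.15 to 1.36), Il6 (2.49), Xirp2 (2.01) and Hsph1 (3.12) had the opposite sign in nuclei, as had Acsl1 (0.668), Fabp3 (0.614) and Ckmt2 (0.569). The medians in tissue and in summed nuclei were 1.11 and -0.25 for fatty acid oxidation, 0.78 and -0.19 for oxidative phosphorylation, -0.71 and 0.63 for extracellular matrix, and -1.58 and 0.23 for cell cycle genes. With the classes summed at equal shares the nuclear medians were 0.16 for extracellular matrix and -0.18 for cell cycle genes, so the sign of the latter rested on the shares. In the Ltbp2 and Hmcn2 clusters of fibroblast-like nuclei the cell cycle medians were -0.08 and 0.13. In tissue and in summed nuclei the medians were -0.99 and -0.75 for macrophage markers and 0.48 and 0.75 for fibroblast markers. They were 0.91 and -0.02 for structural genes and -0.15 and -0.57 for interferon response genes. At equal shares the nuclear medians of these 4 lists were -0.40, 0.17, 0.01 and -0.47, in the same order. Of 5661 genes called in tissue and measured in nuclei, 52.3% had the same sign (45.9% of those higher and 57.7% of those lower with BT2). Across 13976 genes, which are not independent replicates, the log2 ratios correlated at r = 0.207 (Spearman 0.116).

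**Figure D4:**
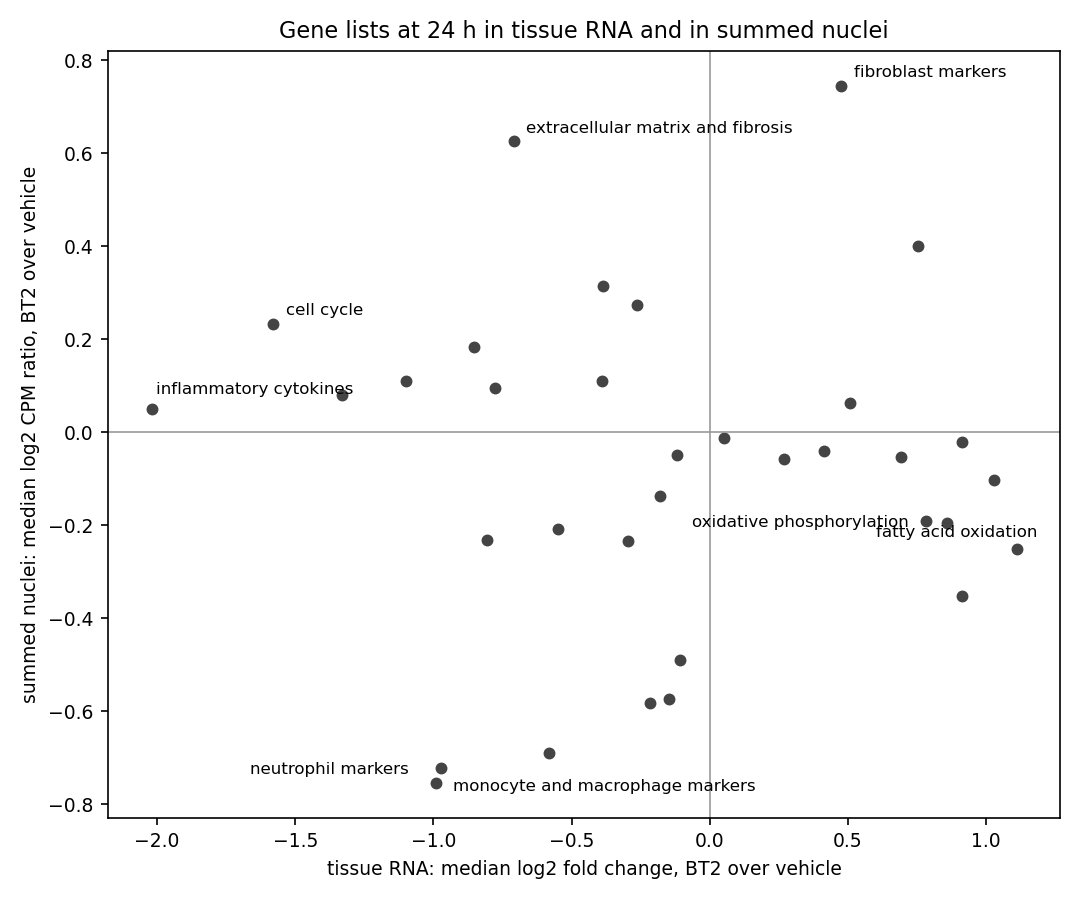
Median log2 ratio of BT2 over vehicle at 24 h for each gene list, over the members measured in both, in tissue RNA (2 libraries per group, x axis) and in summed nuclei (1 library per group, y axis). Fatty acid oxidation lies at 1.11 in tissue and -0.25 in nuclei, and macrophage markers at -0.99 and -0.75.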

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

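The test of library scaling and the test of single pairs of libraries were written before their results were seen, and the other tests of explanations here were chosen only after the result was seen, of which the fit without vehicle replicate 1 and the sums at equal class shares had been planned as alternatives but not as tests.

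The BT2 effect differed between 4 h and 24 h, by the edgeR test of the difference, for the genes that follow. The difference of the log2 fold changes was 2.64 for Enpp2, 2.01 for Gbp1, 1.87 for Gsn, 1.69 for Hfe2 and 1.48 for Sod3. It was -2.19 for Fam105a, -1.92 for Npl, -1.70 for Folr2, -1.68 for Gnpda1 and -1.42 for B4galt6. The difference also passed for 19 of 25 fatty acid oxidation genes and 23 of 28 oxidative phosphorylation genes, which had the higher effect at 24 h, and for 8 of 29 cell cycle genes, which had the lower effect at 24 h. Without vehicle 24 h replicate 2, edgeR called 0 genes for the difference, with 2854 at an unadjusted p under 0.05.

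At 24 h the fatty acid oxidation, oxidative phosphorylation, calcium handling and structural lists were higher with BT2 in tissue RNA by camera with the preset correlation. With an estimated correlation it called 0 lists at 24 h. A larger share of cardiomyocyte RNA as the only change would lower endothelial markers and raise cardiac stress genes, whereas the endothelial median was 0.42 and the cardiac stress median -1.16. These values bear on that single change, and other changes in the mix of cells were not tested. The oxidative phosphorylation median was 0.78 under TMM and 0.82 under upper quartile factors, which argues against the choice between these factors as the cause. That choice moved the median of all genes only from -0.006 to 0.031, so the test had little room to come out otherwise. A scaling error shared by both was not tested. A hypothesis is that BT2 raises or preserves these transcripts within cardiomyocytes, but the fatty acid oxidation median in cardiomyocyte-like nuclei was -0.45, and with 1 nuclear library per group a rise within the cells cannot be told apart from its absence. More surviving cardiomyocytes together with other changes may contribute and stay untested.

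At 24 h the nuclear ratios had the sign of the tissue fold change in 52.3% of the genes called in tissue. Summed at equal class shares it was 56.4%. For the genes higher with BT2 in tissue 45.9% shared the sign, and 44.9% at equal shares, so equal shares did not raise the agreement. The nuclear ratios were not centred. Their median lay below 0 for these genes (-0.0294, and -0.0315 at equal shares) and for the genes lower with BT2 (-0.0572 and -0.0867). Both sign counts therefore depend in part on the zero point, and no conclusion on class shares as the main cause is drawn. For the genes lower with BT2 the percentage rose from 57.7% to 66.1%, between the limits of the test, so a part of the shares cannot be told apart from other causes. At equal shares the nuclear median took the sign of tissue for cell cycle genes (0.23 to -0.18), endothelial markers (-0.04 to 0.19), endothelial adhesion genes (-0.01 to 0.16), hypoxia genes (-0.06 to 0.02) and structural genes (-0.02 to 0.01). It lost that sign for chemokines (-0.23 to 0.01) and glycolysis genes (-0.05 to 0.05), and the matrix median went from 0.63 to 0.16. The correlation of 0.207 across genes was positive, where exchanged labels of the nuclear libraries would lead to a negative one. It comes from the comparison under question, with a limit set after it was seen. Since lists such as fatty acid oxidation had opposite signs in tissue and nuclei, exchanged labels are not excluded. Differences between single samples of the size seen in tissue are argued against by the correlation of ratios from separate single pairs of tissue libraries, which was at least 0.85. This covers differences between animals only if the tissue libraries came from separate animals, which is not stated. Differences between nuclear and tissue polyadenylated RNA, larger ones between animals, and in the dose, which is not given for the tissue samples, may account for the gap and were not tested.

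At 4 h cytokine, chemokine, neutrophil, protease, immediate early and cardiac stress lists were lower with BT2 by camera with the preset correlation. With an estimated correlation it called 0 lists at 4 h. Fewer neutrophils in the BT2 samples could account for the neutrophil, cytokine and protease genes. The neutrophil median was -2.31 with 8 of 13 markers lower. As these markers are part of the pattern, they cannot tell fewer neutrophils apart from lower expression per cell. The cytokine and protease genes were not tested for this. The cardiac stress genes had a median of -1.16, and some of them are made mainly in muscle cells. At 24 h 87.1% of the nuclear UMIs of Xirp2 and 78.5% of those of Nppb lay in cardiomyocyte-like nuclei. For Mthfd2 of the same list 51.6% lay in fibroblast-like nuclei. The loss of neutrophil RNA by itself would not lower such genes, and an indirect effect of fewer neutrophils was not tested. The shallow vehicle replicate 1 is argued against as the cause, since without it the median of each of these 6 lists was -1.02 or lower. Lower activity of the stress pathways within the resident cells stays open and was not tested.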

How the results depend on the processing

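The removal of nuclei with the highest 8% of Scrublet scores was chosen after the data were seen, and the other alternatives were set before. Of 61 gene counts under alternatives 37 stayed within 1.5 times, of 21 list counts 18, and of 62 nuclear shares 55 stayed within their interval. Of 3288 values of named tissue genes 2966 kept their direction and side of the threshold, 313 lost the call, 4 gained it and 5 reversed. Of 413 values of called tissue lists 327 kept the call and 86 lost it. Of 616 nuclear gene values 570, and of 972 nuclear list medians 915, stayed within their spread. These totals include 154 gene values and 257 list medians from centring on the median gene, a constant shift per class that moved 0 of them. Thinning to 1000 UMIs moved 42 of 154 gene values. Of 202 list medians it moved 35 and reversed 4. In the simulation small changes were often missed: at 1.5-fold the recovery was 10.9% at 4 h and 25% at 24 h. The part of depth in this was not separated from that of the spread or the 2 libraries per group. The simulation had 129 and 145 calls, against 2495 and 6016 in the data. The same adjusted p then demands a smaller unadjusted p, so this recovery does not carry over to the data.

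With a minimum of 2-fold, which admits fewer genes by construction, the counts were 931 (BT2 at 4 h), 2262 (BT2 at 24 h), 614 (difference), 3325 (time in vehicle) and 1300 (time with BT2). Without the low-count filter the difference had 1819 genes, and with the 4 h libraries alone BT2 at 4 h had 621. Leaving out 1 library at a time gave edgeR counts from 112 to 2796 (BT2 at 4 h), 2982 to 4558 (BT2 at 24 h), 0 to 1443 (difference), 4629 to 6583 (time in vehicle) and 1025 to 2046 (time with BT2). The count of 0, without vehicle 24 h replicate 2, stood beside 2854 genes at an unadjusted p under 0.05. Lists called by camera with an estimated correlation were 0, 0 and 0 for BT2 at 4 h, BT2 at 24 h and time in vehicle, with 4, 2 and 2 at an unadjusted p under 0.05, and fry called 14, 22 and 22. With the replicate number as a block the gene counts were 2248, 5824, 729, 7011 and 3129 and the list counts 16, 24 and 20. Among genes of at least 5 CPM the effects at 4 h and 24 h correlated at 0.58.

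Leaving out 1 library, Fosb, not past the threshold, ranged from -1.12 to 0.54 at 4 h (0.54 and 0.21 without replicate 2 of vehicle and of BT2). At 24 h it ranged from -1.90 to 0.30 (0.16 and 0.30 without replicate 2 of vehicle and of BT2), and Egr1 from -0.59 (without BT2 replicate 1) to 0.65. At Leiden resolution 0.3 the share ratio was 1.87 for fibroblast-like, 0.462 for neutrophil-like and, reversed, 0.984 for pericyte-like nuclei, and at resolution 1 it was 0.857 for blood endothelial-like nuclei. The strict nuclear limits gave 2.48 for Schwann or neuronal-like, 0.649 for lymphocyte-like and 0.519 for monocyte or macrophage-like nuclei. They gave no value for the neutrophil and dendritic classes. With doublets kept, which added 1 nucleus, the dendritic class also had no value. The monocyte or macrophage-like share in vehicle was then 17.89%, and its share ratio 0.665. At equal class shares the sign shared with tissue was 56.4%. Thinning to 1000 UMIs turned the interferon median in cardiomyocyte-like nuclei to 0.0441, the unfolded protein median in fibroblast-like nuclei to -0.0840, the fibroblast marker median in neutrophil-like nuclei to -0.0938 and the matrix median in pericyte-like nuclei to -0.00215. The chemokine median in neutrophil-like nuclei was 0.14 with doublets kept, and the macrophage marker median in fibroblast-like nuclei 0.0349 without the highest 8% of Scrublet scores. For these changes the cause was not tested.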

Other observations

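These observations were chosen after the values were seen, from lists fixed before. At 24 h, 11 of 21 circadian clock and glucocorticoid target genes were higher with BT2, among them the clock output regulators Hlf (1.89), Dbp (1.44), Per3 (1.26) and Ciart (1.13), while Clock had -0.41 and Arntl -0.81 (edgeR adjusted p = 0.00184 for Hlf, 0.00708 for Dbp, 0.0165 for Clock and 0.0561 for Arntl). At 4 h Dbp had 1.14 and Arntl -1.05 (edgeR adjusted p = 0.0392 and 0.046). Of these genes Per3 alone was refitted with single libraries left out. The hour of day of the sampling is not given in the sources used here.

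The interferon response list had a median below 0 in the nuclei of cardiomyocyte-like (-0.58), blood endothelial-like (-0.49), fibroblast-like (-0.29), monocyte or macrophage-like (-0.56), neutrophil-like (-0.98) and pericyte-like (-0.88) classes at 24 h, with 1 library per group. After thinning to 1000 UMIs the median turned to 0.0441 in cardiomyocyte-like nuclei (6 members left of 21) and was -0.0761 in fibroblast-like nuclei (percentile 54.63). In the other 4 classes it stayed at or below -0.37. RNA carried over from other cells is not excluded in any of these classes. In tissue at 24 h the median of the interferon response list was -0.15, with Oasl2 lower (-1.01) and Gbp1 higher (1.35). Camera did not call the list there, and DESeq2 called 2 of 32 members higher and 6 lower.

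Of the aryl hydrocarbon receptor targets, Cyp1b1 was higher with BT2 at 4 h (2.38 ± 0.48, edgeR adjusted p = 0.0215), a call that ended without vehicle replicate 2 (adjusted p = 0.145) and without BT2 replicate 2. Cyp1a1 had 9 and 8 raw counts in the vehicle libraries at 4 h and 24 and 1472 with BT2, and did not pass (edgeR adjusted p = 0.0891). Aldh3a1 was higher at 24 h (3.06, edgeR adjusted p = 0.000802), with 25 and 17 raw counts in vehicle and 136 and 174 with BT2. Nqo1 and Tiparp had 0.11 and 0.04 at 4 h and did not pass.

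Fam111a, singled out after its values were seen, had raw counts of 41 and 16 in vehicle and 4202 and 31 with BT2 at 4 h, and of 519 and 369 in vehicle and 3123 and 169 with BT2 at 24 h. In blood endothelial-like nuclei it had 1247 UMIs in vehicle and 7 with BT2. As its counts differed widely between libraries of one group, a variant carried by single animals is not excluded for this gene and was not tested.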
